A study of Homo sapiens with 36 samples.

How the data were processed

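HK-2 cells had been treated at near confluency with CdCl, Di or Kbr, or with vehicle, and total RNA was isolated with a column kit and turned into biotinylated cRNA for single-colour Affymetrix arrays, per the labels' protocols. The deposited values were log2 expression per probe set, made by the authors with GCRMA, a method that corrects background with probe sequence and normalizes between arrays, per the submitters' processing notes. Its version and settings are not given in the sources used here, and the array readings before that step were not used here. The values ran from 0.714 to 16.1, the medians of the 36 arrays lay between 2.91 and 3.02, and no array was a copy of another. Such values hold a floor of background signal, so differences of dim genes are compressed, and a change shared by most genes is partly removed by the normalization.

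Groups, replicate numbers and times were taken from the sample descriptions. Each of the 54675 probe sets was kept if its value was above 4 on at least 3 of the 36 arrays, and 62 control probe sets were left out. Between 38.3% and 39.8% of the probe sets of an array lay above that level. The platform annotation named 1 gene for 41091 probe sets, several for 1801 and none for 11721. Matching gene identifiers to a current gene table changed 0 symbols, and 54 probe sets had an identifier that table did not hold. Of 23599 probe sets kept, those with several genes or none (3155) were not used. For each gene the probe set with the highest mean over all arrays was used, which left 11092 genes, of which 5474 had several kept probe sets. Y-linked genes and XIST, 5 of the genes tested, stayed in the tests and counts but are not named. Where the lower group averaged under the floor of 4, a fold is given as at least the higher group's mean over that floor.

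All 36 arrays entered one linear model with 12 group means in limma 3.58.1 under R 4.3.3, with moderated tests (lmFit and eBayes), Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Comparisons were each treatment against the control of its set and time, the doses of Kbr, CdCl against Di, the change of each effect over time, the CdCl and Di effects against that of high Kbr at 48 h, the 48 h controls of the sets, and genes changed alike by all 3 compounds at 48 h. SEs are those of the model, so a gene has the same SE in every comparison of one group with another. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists of a comparison, and again with the correlation estimated. The lists were NRF2 targets, metallothioneins and zinc response, heat shock response, endoplasmic reticulum chaperones and XBP1/ATF6 targets, ATF4 targets and amino acid response, p53 targets, DNA replication and G1/S, G2/M and mitosis, base excision repair, cholesterol synthesis, glycolysis and hypoxia response, oxidative phosphorylation, proximal tubule markers, kidney injury markers, NF-kB targets and cytokines, interferon-stimulated genes, immediate early genes and MAPK feedback, lysosome and autophagy, proteasome subunits, ribosome biogenesis, apoptosis regulators, extracellular matrix and TGF-beta response, distal nephron markers, and fibroblast, endothelial and leukocyte markers. Fewer than 80% of members were measured for cholesterol synthesis (75%), interferon (79.2%), apoptosis (73.7%), extracellular matrix (73.1%), proximal tubule (27.6%), distal nephron (21.4%) and the fibroblast, endothelial and leukocyte markers (16.7%).

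Genes are named by a rule. For comparisons with control these were 21 index genes, of which HSPA1A was not measured here, the 6 largest rises and falls past the test whose groups did not overlap (a separation that chance gives in 10% of genes with 3 arrays against 3), and the 3 largest passing members of each list. For the others they were index genes past the test and the 4 largest each way. Not all genes the rule allows are named. The tests were checked on simulated arrays with known changes: across comparisons, 34.3% to 43.3% of genes changed by 0.5 on the log2 scale were recovered, 82.1% to 91.0% of those changed by 1 and 98.5% to 100% of those changed by 2. Simulated comparisons called 151 to 160 genes, with noise independent between genes and arrays, while the real ones with control called 695 to 6855. These rates hold for that setting and do not give the sensitivity of the real comparisons.

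The labels number the replicates 1 to 3 in every group. In the Kbr set the deviations of same-numbered arrays from their group means correlated in all 45 pairs (r = 0.218 to 0.701, against a median of -0.226 for arrays of different numbers), and each of the 18 arrays lay closest to its own number. The numbers were therefore taken to pair these arrays, on the data alone, and blocked values are given beside results that they move. Alternatives were no filter, a filter at 6, a variance trend, quantile normalization, median centring, the mean of a gene's probe sets, only the compared groups in the fit, array weights, the replicate block, a threshold of 0.01, each array left out in turn and, for lists, camera with the correlation estimated and the rotation test fry. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The design, lists, naming rule and all but a few alternatives were fixed before the data were examined.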

Results

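Gene expression was measured on 36 single-colour arrays in HK-2 cells, an immortalized line of human renal proximal tubular epithelium, the part of the nephron that takes back most of what the kidney filters. The cells had been exposed to 3 compounds that the labels call CdCl, Di and Kbr, names they do not spell out, or to vehicle. The series set out to find signatures of toxicity in these cells, and its title counts the 3 compounds among those it calls Tox 2, one of the classes its authors had drawn from clustered expression profiles. The arrays formed 2 sets of 18, each with its own controls. In one set, cells received CdCl, Di or vehicle for 12 h or 48 h. In the other, they received Kbr at a dose given only as low or high, or vehicle, for 24 h or 48 h. Each of the 12 groups held 3 biological replicates per the labels, and the number of arrays limits the precision of every value here. Arrays of the same group correlated at r = 0.982 to 0.995 across the kept probe sets, and arrays of different groups at 0.891 to 0.993. The 3' minus 5' difference of the beta-actin probe sets, a sign of RNA quality, averaged between 1.40 and 1.84 log2 units in the groups of the CdCl and Di set and between 0.87 and 1.06 in those of the Kbr set.

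After 12 h of CdCl, genes of the oxidative stress, metal and heat shock responses stood far above control. HMOX1, which encodes the haem-degrading enzyme heme oxygenase-1, was higher by 6.43 ± 0.19 on the log2 scale (difference ± SE, 3 arrays against 3, as for every value below), and ATF3, a stress-induced transcription factor, by 7.35 ± 0.69. The median over all genes lay at -0.16 in this comparison and moved by 0.16 once arrays were centred, so its log2 differences are given relative to that median. ZFAND2A, a gene induced by heat and arsenite, rose by 6.95 ± 0.22, and HSPA6, an inducible member of the HSP70 chaperones, was at least 158-fold higher than in control, where its probe set was at background. All 16 measured members of the heat shock response list rose (16 up, 0 down adjusted over the list alone), among them the co-chaperones DNAJB1 (3.36 ± 0.22) and BAG3 (3.22 ± 0.15), and a competitive set test gave adjusted p = 1.42e-23 (adjusted p = 4.89e-05 with an estimated correlation). Of 30 NRF2 targets, genes of the antioxidant response, 25 rose and 0 fell (25 up, 0 down adjusted over the list alone). They included GCLM, a subunit of the enzyme that limits glutathione synthesis (3.08 ± 0.15), and the cystine transporter SLC7A11 (4.86 ± 0.43), and the list test gave adjusted p = 1.04e-24 (adjusted p = 4.89e-05 with an estimated correlation). Among 9 metallothionein and zinc response genes, 8 rose (8 up, 0 down adjusted over the list alone), with adjusted p = 8.92e-15 (adjusted p = 0.00541 with an estimated correlation). MT1M rose by 4.85 ± 0.23 and MT1X by 2.05 ± 0.14. Probe sets of the MT1, HSP70 and AKR1C families can bind transcripts of near-identical copies, so the member named is uncertain wherever one is given.

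Genes of glycolysis and the hypoxia response rose with CdCl at 12 h as well: 18 of 23 passed upward (18 up, 0 down adjusted over the list alone), with adjusted p = 2.33e-15 (adjusted p = 0.000157 with an estimated correlation). Among them were the glucose transporter SLC2A1 (2.64 ± 0.13), hexokinase HK2 (2.39 ± 0.17) and the vasodilator peptide ADM (3.66 ± 0.21). Cytokine and NF-kB target genes did so in 10 of 20 cases against 2 that fell (13 up, 2 down adjusted over the list alone), with adjusted p = 1.39e-05 (adjusted p = 0.0142 with an estimated correlation). IL6 rose by 2.86 ± 0.53 and the NF-kB inhibitor TNFAIP3 by 3.29 ± 0.28. Endoplasmic reticulum chaperones and XBP1/ATF6 targets rose in 15 of 17 (16 up, 0 down adjusted over the list alone), as did 12 of 27 ATF4 targets, of which 1 fell (12 up, 1 down adjusted over the list alone). HSPA5, the main chaperone of that compartment, was higher by 1.65 ± 0.28 and the stress transcription factor DDIT3 by 3.89 ± 0.58. The set test gave adjusted p = 9.49e-10 (adjusted p = 0.142 with an estimated correlation) for the former list and adjusted p = 2.42e-06 (adjusted p = 0.397 with an estimated correlation) for the latter, so neither call held with an estimated correlation. In the other direction, 26 of 27 genes of DNA replication and G1/S fell and 1 rose (1 up, 26 down adjusted over the list alone), and 32 of 33 genes of G2/M and mitosis fell (0 up, 32 down adjusted over the list alone). Examples were the uracil glycosylase UNG (-1.55 ± 0.13), cyclin E2, CCNE2 (-1.36 ± 0.16), the DNA helicase BLM (-2.73 ± 0.30) and the spindle protein HMMR (-1.16 ± 0.12). The tests gave adjusted p = 8.03e-12 (adjusted p = 0.00541 with an estimated correlation) for replication and adjusted p = 1.34e-12 (adjusted p = 0.0319 with an estimated correlation) for mitosis. Over all 11092 genes, 4870 passed, 1484 higher and 3386 lower, with 1022 at least 2-fold changed. With each array centred on its median, 4107 passed, 2094 higher and 2013 lower.

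At 48 h of CdCl, HMOX1 was 75.3-fold above control (log2 6.23 ± 0.19), and metallothioneins were among the largest rises, with MT1M 74.1-fold and MT1X 6.19-fold higher (log2 6.21 ± 0.23 and 2.63 ± 0.14). In that list 8 of 9 members rose and 1 fell (8 up, 1 down adjusted over the list alone), with adjusted p = 2.98e-12 (adjusted p = 0.0134 with an estimated correlation). NRF2 targets rose in 24 of 30 and fell in 1 (25 up, 1 down adjusted over the list alone), with adjusted p = 3.11e-13 (adjusted p = 0.00320 with an estimated correlation). They included the quinone reductase NQO1 (2.57 ± 0.13) and GCLM (2.92 ± 0.15). Heat shock genes rose in 14 of 16 (14 up, 0 down adjusted over the list alone), with adjusted p = 4.27e-10 (adjusted p = 0.00715 with an estimated correlation). DNAJB1 rose by 2.10 ± 0.22. Lysosome and autophagy genes rose in 12 of 19 (12 up, 0 down adjusted over the list alone), with adjusted p = 5.12e-05 (adjusted p = 0.0364 with an estimated correlation). Among them were the autophagosome protein MAP1LC3B (1.16 ± 0.16) and the protease cathepsin L, CTSL (2.83-fold). Replication genes fell in 25 of 27 (1 up, 25 down adjusted over the list alone) and mitotic genes in 29 of 33 (0 up, 29 down adjusted over the list alone). The licensing factor CDT1 (-2.90 ± 0.13), the helicase subunit MCM5 (-2.13 ± 0.14) and the kinase CDK1 (-1.57 ± 0.16) were among them. For replication the set test gave adjusted p = 5.07e-17 (adjusted p = 0.00274 with an estimated correlation) and for mitosis adjusted p = 5.97e-13 (adjusted p = 0.0364 with an estimated correlation).

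With CdCl at 48 h the bicarbonate cotransporter SLC4A4 lay at -3.14 ± 0.23 relative to control, the cystine and dibasic amino acid transporter SLC3A1 at -2.25 ± 0.26 and the kidney cadherin CDH6 at -2.15 ± 0.22. Of the 8 proximal tubule markers measured, out of 29 listed, 5 fell and 2 rose (2 up, 5 down adjusted over the list alone), with adjusted p = 0.0244 (adjusted p = 0.211 with an estimated correlation). The thiol methyltransferase TMT1A had one of the largest falls (-4.90 ± 0.44). Among 16 kidney injury markers 4 rose and 4 fell (4 up, 4 down adjusted over the list alone), with LCN2 at 2.85 ± 0.13 and HAVCR1 at -1.02 ± 0.16, and that list's test did not pass, at adjusted p = 0.815 (adjusted p = 0.898 with an estimated correlation). Its median was 0.04 and its mean -0.02. In all, 4735 genes passed, 2292 higher and 2443 lower (2436 and 2298 of 4734 after median centring), 1194 of them at least 2-fold. Endoplasmic reticulum chaperones passed upward in 6 of 17 and downward in 0 (6 up, 0 down adjusted over the list alone), with adjusted p = 0.0439 (adjusted p = 0.726 with an estimated correlation). That call was lost with the rotation test (adjusted p = 0.0836), after quantile normalization (adjusted p = 0.0798), without control replicate 2 or 3 (adjusted p = 0.0684 or 0.0598) and without CdCl replicate 2 or 3 (adjusted p = 0.0738 or 0.0509). ATF4 targets went both ways, 4 up and 7 down of 27 (4 up, 6 down adjusted over the list alone), and did not pass as a list, at adjusted p = 0.627 (adjusted p = 0.898 with an estimated correlation). HSPA5 (0.19 ± 0.28, adjusted p = 0.625) and DDIT3 (0.23 ± 0.58, adjusted p = 0.783) did not pass at this time, when the control itself averaged 13.06 for DDIT3, against 8.07 at 12 h. The SE of DDIT3 carries the wide spread of the Kbr groups at 48 h (SDs of 1.12 to 1.87). Its SD at 48 h was 0.15 with CdCl and 0.06 in the control of CdCl.

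With Di at 12 h, TXNIP, an inhibitor of thioredoxin, fell by 2.20 ± 0.43, and thioredoxin reductase TXNRD1 rose by 0.92 ± 0.11. The glutathione gene GCLM rose by 0.80 ± 0.15, the sulfiredoxin SRXN1 by 0.71 ± 0.16, the cell cycle inhibitor CDKN1A by 0.52 ± 0.10 and the apoptosis regulator BAX by 1.28 ± 0.25. HAVCR1, a marker of tubular injury, rose by 1.07 ± 0.16. Of 30 NRF2 targets 6 passed upward (7 up, 0 down adjusted over the list alone), with adjusted p = 3.28e-06 (adjusted p = 0.167 with an estimated correlation). Among 9 metallothionein and zinc response genes none passed in either direction, and MT1X differed by 0.07 ± 0.14 (adjusted p = 0.840). Mitotic genes fell in 4 of 33 (0 up, 4 down adjusted over the list alone), with adjusted p = 0.00379 (adjusted p = 0.492 with an estimated correlation). HMMR fell by 0.62 ± 0.12. A set test also placed the 27 proteasome subunits above other genes although 0 passed alone, with a median of 0.13 and adjusted p = 8.46e-05 (adjusted p = 0.492 with an estimated correlation). By the rotation test the mitotic list had adjusted p = 0.0517 and the proteasome list adjusted p = 0.302. In all 695 genes passed, 185 higher and 510 lower, with 59 at least 2-fold changed. That split was 293 to 253 after median centring and 236 to 362 after quantile normalization, of 546 and 598 genes. Leaving out one array moved the count to 309 (control replicate 2), 286 (control replicate 3), 353 (Di replicate 2) or 452 (Di replicate 3). It was 298 with only the compared groups in the fit, 1446 with the CdCl and Di set fitted alone, 1662 with the replicate block and 2394 with array weights. The beta-actin 3' minus 5' value averaged 1.40 with Di (SD 0.16) and 1.84 in control (SD 0.14). Di replicate 2 stood apart, at 1.22 for that value and with a mean r of 0.986 to its own group.

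By 48 h, Di had raised nearly every NRF2 target measured: 29 of 30 rose and 0 fell (29 up, 0 down adjusted over the list alone). HMOX1 was 46.4-fold above control (log2 5.54 ± 0.19), SRXN1 16.8-fold (4.07 ± 0.16) and NQO1 12.4-fold (3.63 ± 0.13), and the list test gave adjusted p = 5.23e-28 (adjusted p = 3.77e-05 with an estimated correlation). MAP2, a microtubule-associated protein best known from neurons, was 34.0-fold higher. Heat shock genes rose in 14 of 16 and fell in 1 (14 up, 1 down adjusted over the list alone), with adjusted p = 2.75e-10 (adjusted p = 0.00618 with an estimated correlation). DNAJB1 rose by 2.00 ± 0.22. Among 24 p53 targets 10 rose and 1 fell (10 up, 1 down adjusted over the list alone), with adjusted p = 0.000830 (adjusted p = 0.0226 with an estimated correlation). CDKN1A rose by 1.84 ± 0.10, the stress cytokine GDF15 by 2.17 ± 0.19 and MDM2 by 0.76 ± 0.16. In the metallothionein list 8 of 9 members fell and 1 rose (1 up, 8 down adjusted over the list alone), with adjusted p = 0.000208 (adjusted p = 0.195 with an estimated correlation). MT1X fell by 1.34 ± 0.14 and MT2A fell by 1.07 ± 0.12. Every one of the 33 mitotic genes fell (0 up, 33 down adjusted over the list alone), as did 25 of 27 replication genes (0 up, 25 down adjusted over the list alone). The ribonucleotide reductase subunit RRM2 (-3.22 ± 0.10), MCM7 (-3.08 ± 0.17) and cyclin B1, CCNB1 (-0.97 ± 0.11) were examples. The set test gave adjusted p = 9.06e-21 (adjusted p = 0.00767 with an estimated correlation) for mitosis and adjusted p = 3.19e-18 (adjusted p = 0.00107 with an estimated correlation) for replication.

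Proximal tubule markers fell with Di at 48 h in 6 of 8 and rose in 1 (1 up, 7 down adjusted over the list alone), with adjusted p = 0.000215 (adjusted p = 0.0226 with an estimated correlation). CDH6 fell by 3.54 ± 0.22, SLC4A4 fell by 3.22 ± 0.23 and SLC3A1 fell by 2.98 ± 0.26. CLDN2, a pore-forming claudin of the proximal tubule, was at least 35.6-fold lower. The adhesion molecule VCAM1 fell by 4.45 ± 0.28 and HAVCR1 fell as well (adjusted p = 1.50e-08), while LCN2 rose by 2.00 ± 0.13. Interferon-stimulated genes fell in 9 of 19 and rose in 1 (2 up, 9 down adjusted over the list alone), with IFI44L at -2.12 ± 0.57, without passing as a list, at adjusted p = 0.0856 (adjusted p = 0.516 with an estimated correlation). Apoptosis regulators went both ways, 5 up and 3 down of 14 (5 up, 3 down adjusted over the list alone), among them PMAIP1 at 1.40 ± 0.20, and did not pass as a list, at adjusted p = 0.177 (adjusted p = 0.349 with an estimated correlation). In all, 4773 genes passed, 2122 higher and 2651 lower (2572 and 2342 of 4914 after median centring), 1424 at least 2-fold.

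**Figure D1:**
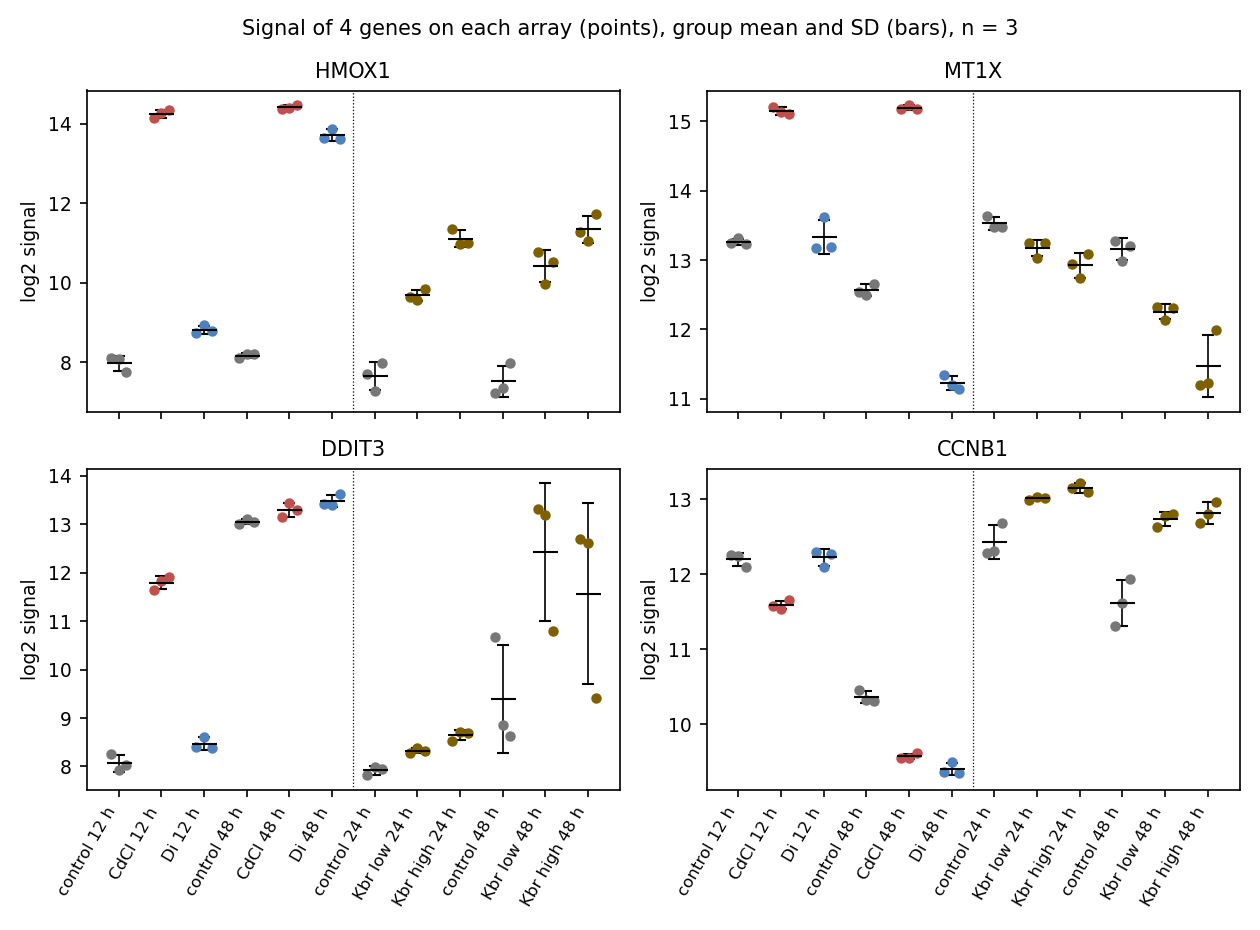
Log2 signal of HMOX1, MT1X, DDIT3 and CCNB1 on each of the 36 arrays, by group, with points for single arrays and bars for the group mean and SD (n = 3); the dotted line parts the CdCl and Di set from the Kbr set. HMOX1 averages 14.41 with CdCl and 8.17 in its control at 48 h, and DDIT3 averages 8.07 in that set's control at 12 h and 13.06 at 48 h.

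At the high dose of Kbr, 24 h of exposure raised HMOX1 10.9-fold (log2 3.45 ± 0.19), GCLM 5.49-fold (2.46 ± 0.15) and SLC7A11 4.70-fold (2.23 ± 0.43). NRF2 targets rose in 23 of 30 and fell in 1 (26 up, 2 down adjusted over the list alone), with adjusted p = 1.11e-14 (adjusted p = 0.00312 with an estimated correlation). Heat shock genes rose in 13 of 16 (13 up, 0 down adjusted over the list alone), with adjusted p = 1.39e-11 (adjusted p = 0.00425 with an estimated correlation). BAG3 rose by 1.57 ± 0.15 and the HSP90 co-chaperone CHORDC1 by 1.91 ± 0.15. Ribosome biogenesis genes rose in 13 of 15 (13 up, 0 down adjusted over the list alone), with adjusted p = 2.19e-07 (adjusted p = 0.0417 with an estimated correlation). RRP12 rose by 0.91 ± 0.25. Proteasome subunits rose in 23 of 27 (23 up, 0 down adjusted over the list alone), with adjusted p = 8.29e-11 (adjusted p = 0.170 with an estimated correlation). With both the estimated correlation and the replicate block the set test gave adjusted p = 0.0305. PSMD12 rose by 1.14 ± 0.15. Mitotic genes rose in 18 of 33 (22 up, 0 down adjusted over the list alone), with adjusted p = 3.27e-07 (adjusted p = 0.207 with an estimated correlation). CCNB1 rose by 0.72 ± 0.11 and CDK1 by 0.77 ± 0.16. Genes of cholesterol synthesis fell in 13 of 18 (0 up, 13 down adjusted over the list alone), with adjusted p = 0.000141 (adjusted p = 0.0533 with an estimated correlation). The sterol reductase TM7SF2 fell by 1.83 ± 0.22. Further falls were those of SCEL, a gene of stratified epithelia (-3.41 ± 0.31), TXNIP (-2.91 ± 0.43) and SLC3A1 (-2.13 ± 0.26). In all, 4517 genes passed, 1711 higher and 2806 lower, 850 at least 2-fold, and median centring gave 4500, 2293 higher and 2207 lower.

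At 48 h the same dose changed 6855 genes, the most of any comparison with control in the fit of all 36 arrays. Of these 3031 were higher and 3824 lower (3509 and 3373 of 6882 after median centring), and 2596 were at least 2-fold changed. With only the compared groups in the fit 5605 passed, against 5823 for CdCl at 12 h. HMOX1 stood 14.2-fold above control (log2 3.82 ± 0.19), ATF3 21.6-fold (4.43 ± 0.69), ADM 18.3-fold (4.19 ± 0.21) and the endoplasmic reticulum protein SDF2L1 15.0-fold (3.90 ± 0.53). Without high-dose replicate 3 the log2 values were 5.68 for ATF3 and 4.77 for SDF2L1, and for ATF3 they were 3.64 without high-dose replicate 1 and 5.02 without control replicate 1. NRF2 targets rose in 26 of 30 and fell in 2 (27 up, 3 down adjusted over the list alone), with adjusted p = 1.78e-09 (adjusted p = 0.0307 with an estimated correlation). Heat shock genes rose in 14 of 16 and fell in 1 (14 up, 1 down adjusted over the list alone), with adjusted p = 2.33e-07 (adjusted p = 0.0417 with an estimated correlation), the latter 0.0560 under the replicate block. CHORDC1 rose by 2.75 ± 0.15. Endoplasmic reticulum chaperones rose in 14 of 17 (14 up, 0 down adjusted over the list alone), with adjusted p = 0.000848 (adjusted p = 0.437 with an estimated correlation). HSPA5 rose by 1.81 ± 0.28. All 15 ribosome biogenesis genes rose (15 up, 0 down adjusted over the list alone), with adjusted p = 1.04e-06 (adjusted p = 0.0639 with an estimated correlation). Of 27 proteasome subunits 26 rose (26 up, 0 down adjusted over the list alone), with adjusted p = 2.69e-09 (adjusted p = 0.194 with an estimated correlation), and PSMD12 was higher by 1.97 ± 0.15. Mitotic genes rose in 28 of 33 and fell in 1 (28 up, 1 down adjusted over the list alone), with adjusted p = 1.04e-06 (adjusted p = 0.205 with an estimated correlation). CCNB1 rose by 1.20 ± 0.11 and KIF2C by 1.39 ± 0.10. In the control the median of that list changed by -0.65 from 24 h to 48 h. Replication genes split evenly, 7 up and 7 down of 27 (7 up, 7 down adjusted over the list alone), the licensing factor CDC6 among the rises (2.88 ± 0.22), and their list did not pass, at adjusted p = 0.317 (adjusted p = 0.663 with an estimated correlation). NEIL3, a DNA glycosylase of cycling cells, rose by 2.31 ± 0.22.

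Among the falls with high Kbr at 48 h, metallothionein and zinc response genes fell in 8 of 9 (0 up, 8 down adjusted over the list alone), with adjusted p = 0.000223 (adjusted p = 0.206 with an estimated correlation). MT1X fell by 1.69 ± 0.14. Cholesterol synthesis genes fell in 14 of 18 and rose in 2 (2 up, 14 down adjusted over the list alone), with adjusted p = 0.00390 (adjusted p = 0.185 with an estimated correlation). LSS fell by 1.68 ± 0.11. Oxidative phosphorylation genes fell in 21 of 36 and rose in 1 (1 up, 21 down adjusted over the list alone), with adjusted p = 0.0120 (adjusted p = 0.365 with an estimated correlation). Of complex I, NDUFS7 fell by 1.96 ± 0.15 and NDUFV1 fell by 1.10 ± 0.16. Proximal tubule markers fell in 7 of 8 (1 up, 7 down adjusted over the list alone), with adjusted p = 0.00335 (adjusted p = 0.130 with an estimated correlation). CDH6 fell by 2.56 ± 0.22 and SLC3A1 fell by 2.90 ± 0.26. Extracellular matrix and TGF-beta response genes fell in 13 of 19 and rose in 1 (1 up, 13 down adjusted over the list alone), with adjusted p = 0.0109 (adjusted p = 0.315 with an estimated correlation). Collagen COL1A1 fell by 2.58 ± 0.22. Few markers of other cell types were measured: 2 of 3 distal nephron markers fell (0 up, 2 down adjusted over the list alone) and 2 of 3 fibroblast, endothelial and leukocyte markers did (0 up, 2 down adjusted over the list alone). Among the latter were the matrix proteoglycans DCN (-1.94 ± 0.15) and LUM (-1.92 ± 0.26), and neither list passed, each at adjusted p = 0.138 (adjusted p = 0.246 with an estimated correlation). SCEL was at least 46.7-fold lower, KRT20, an epithelial keratin, fell too (adjusted p = 3.16e-11), and HAVCR1 fell by 1.83 ± 0.16.

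The low dose of Kbr at 24 h raised HMOX1 4.06-fold (log2 2.02 ± 0.19), GCLM 3.56-fold (1.83 ± 0.15) and TRIM16, a further gene of the oxidative stress response, 3.66-fold (1.87 ± 0.14). NRF2 targets rose in 18 of 30 and fell in 1 (21 up, 1 down adjusted over the list alone), with adjusted p = 5.67e-16 (adjusted p = 0.00188 with an estimated correlation). Heat shock genes rose in 11 of 16 (13 up, 0 down adjusted over the list alone), with adjusted p = 3.91e-12 (adjusted p = 0.00329 with an estimated correlation). CHORDC1 rose by 1.31 ± 0.15. Ribosome biogenesis genes passed upward in 8 of 15 cases (11 up, 0 down adjusted over the list alone), with adjusted p = 1.94e-07 (adjusted p = 0.0427 with an estimated correlation). Proteasome subunits did in 16 of 27 (20 up, 0 down adjusted over the list alone), with adjusted p = 2.53e-11 (adjusted p = 0.126 with an estimated correlation). Mitotic genes rose in 11 of 33 (19 up, 0 down adjusted over the list alone), with adjusted p = 1.13e-09 (adjusted p = 0.114 with an estimated correlation), and CCNB1 was higher by 0.59 ± 0.11. With the replicate block and an estimated correlation the proteasome list had adjusted p = 0.0198 and the mitotic list adjusted p = 0.0298. VCAM1 (-2.34 ± 0.28), SCEL (-2.26 ± 0.31) and TXNIP (-2.19 ± 0.43) were among the larger falls. In all, 1687 genes passed, 769 higher and 918 lower, 192 at least 2-fold, and 2720 with the replicate number as a block, 1170 higher and 1550 lower. With only the compared groups in the fit the count was 267, CCNB1 not among them, and with the Kbr set fitted alone 933. Without control replicate 1 the count was 824, and without low-dose replicate 3 it was 997.

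At 48 h the low dose raised ATF3 23.6-fold (log2 4.56 ± 0.69), SDF2L1 15.7-fold (3.97 ± 0.53), DDIT3 8.22-fold (3.04 ± 0.58) and HMOX1 7.47-fold (2.90 ± 0.19). Without low-dose replicate 3 the log2 values were 5.39 for ATF3, 4.96 for SDF2L1 and 3.86 for DDIT3. Without control replicate 1, ATF3 stood at 5.15 and DDIT3 at 3.68, and without low-dose replicate 1 SDF2L1 stood at 3.28. Endoplasmic reticulum chaperones rose in 14 of 17 (14 up, 0 down adjusted over the list alone) and ATF4 targets in 18 of 27 (20 up, 0 down adjusted over the list alone). The set test gave adjusted p = 4.93e-05 (adjusted p = 0.319 with an estimated correlation) for the chaperones and adjusted p = 5.23e-06 (adjusted p = 0.333 with an estimated correlation) for the ATF4 targets. Over all groups of the Kbr set, replicates 1, 2 and 3 deviated from their group means by an average of 0.35, -0.01 and -0.33 in ATF4 targets and of 0.28, 0.03 and -0.31 in the chaperones. NRF2 targets rose in 23 of 30 and fell in 1 (24 up, 1 down adjusted over the list alone), with adjusted p = 2.19e-11 (adjusted p = 0.0126 with an estimated correlation). NQO1 rose by 2.80 ± 0.13. Heat shock genes rose in 12 of 16 (13 up, 0 down adjusted over the list alone), with adjusted p = 3.14e-06 (adjusted p = 0.0690 with an estimated correlation). Immediate early and MAPK feedback genes rose in 11 of 18 and fell in 4 (11 up, 4 down adjusted over the list alone), with adjusted p = 0.00704 (adjusted p = 0.195 with an estimated correlation). The growth factor HBEGF rose by 2.15 ± 0.29 and the phosphatase DUSP5 by 2.16 ± 0.16. Mitotic genes rose in 27 of 33 (27 up, 0 down adjusted over the list alone), with adjusted p = 2.26e-07 (adjusted p = 0.122 with an estimated correlation), against the same control. CCNB1 rose by 1.12 ± 0.11. Metallothionein and zinc response genes fell in 8 of 9 (0 up, 8 down adjusted over the list alone), with adjusted p = 4.79e-05 (adjusted p = 0.122 with an estimated correlation). MT1X fell by 0.90 ± 0.14. Proximal tubule markers fell in 7 of 8 (0 up, 7 down adjusted over the list alone), with adjusted p = 0.000917 (adjusted p = 0.0757 with an estimated correlation). With both the estimated correlation and the replicate block the set test gave adjusted p = 0.0452. The kidney injury list fell in 10 of 16 (1 up, 10 down adjusted over the list alone), with adjusted p = 0.00889 (adjusted p = 0.122 with an estimated correlation). KRT20 fell by 1.39 ± 0.32 and HAVCR1 fell by 1.06 ± 0.16. SCEL (-3.96 ± 0.31) and the matrix protein EFEMP1 (-3.93 ± 0.23) were among the largest falls. In all, 5212 genes passed, 2642 higher and 2570 lower (2501 and 2696 of 5197 after median centring), 1150 at least 2-fold, and 3445 passed with only the compared groups in the fit.

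**Figure D2:**
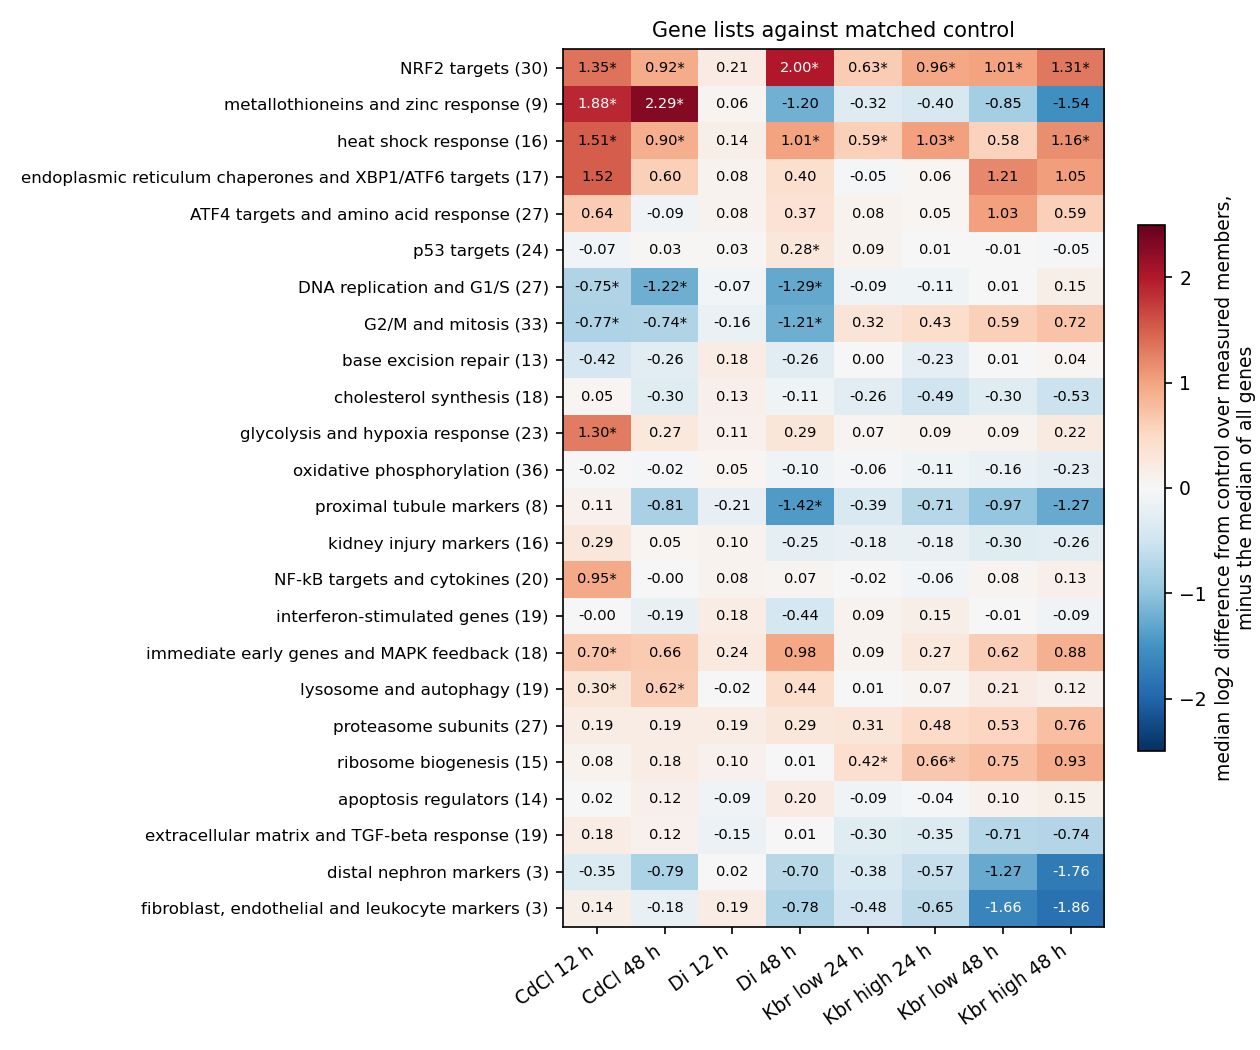
Median log2 difference from matched control over the measured members of each of 24 gene lists (number measured in brackets), minus the median of all genes, in the 8 comparisons with control (n = 3 arrays per group); an asterisk marks lists past the test both with the preset and with an estimated correlation. NRF2 targets carry one in all columns but Di at 12 h, and the metallothionein median lies above 0 with CdCl and below 0 with Di and with both doses of Kbr at 48 h.

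The 2 doses of Kbr were compared directly at each time. At 24 h HMOX1 was 2.69-fold higher with the high dose (log2 1.43 ± 0.19), and the transcription factor HLF lay lower, at -1.55 ± 0.27. NRF2 targets were higher in 5 of 30 (8 up, 0 down adjusted over the list alone) and heat shock genes in 5 of 16 (8 up, 0 down adjusted over the list alone), each at adjusted p = 7.02e-10 (adjusted p = 0.0142 with an estimated correlation). Cholesterol synthesis genes were lower in 3 of 18 (0 up, 5 down adjusted over the list alone), with adjusted p = 0.00231 (adjusted p = 0.151 with an estimated correlation). In all, 487 genes differed, 76 higher and 411 lower with the high dose, 178 and 218 of 396 after median centring, and 1171 with the replicate block (219 and 952). It was 38 with only the compared groups in the fit, HLF not among them, and 108 with the Kbr set fitted alone. Without high-dose replicate 1, 2 or 3 the count was 246, 311 or 305, and without low-dose replicate 1 or 2 it was 196 or 299.

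At 48 h the median of all genes between the doses moved by 0.13 with centring, from -0.06 to 0.06, and values are given relative to it. KRT20 lay lower with the high dose, at -2.54 ± 0.32, as did the chemokine CXCL8 (-0.90 ± 0.19), MT1X (-0.72 ± 0.14) and HAVCR1 (-0.70 ± 0.16), while HMOX1 was higher by 0.99 ± 0.19. Heat shock genes were higher in 10 of 16 (11 up, 1 down adjusted over the list alone), with adjusted p = 8.02e-08 (adjusted p = 0.0493 with an estimated correlation), the latter 0.128 under the replicate block. Metallothionein and zinc response genes were lower in 6 of 9 (0 up, 6 down adjusted over the list alone) and cholesterol synthesis genes in 8 of 18 (0 up, 8 down adjusted over the list alone). The set test gave adjusted p = 0.00306 (adjusted p = 0.409 with an estimated correlation) for the former list and adjusted p = 0.00262 (adjusted p = 0.280 with an estimated correlation) for the latter. In all, 2638 genes differed, 716 higher and 1922 lower, and 2729 after median centring, 1492 higher and 1237 lower. With only the compared groups in the fit 647 differed, and CXCL8, MT1X, HAVCR1 and HMOX1 did not pass.

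CdCl and Di, which shared their controls, were also compared directly. At 12 h ZFAND2A (6.32 ± 0.22), ATF3 (6.37 ± 0.69), HMOX1 (5.43 ± 0.19) and DDIT3 (3.33 ± 0.58) were higher with CdCl, and BLM (-2.65 ± 0.30) and CCNB1 (-0.63 ± 0.11) lower. CdCl exceeded Di in 24 of 30 NRF2 targets (25 up, 0 down adjusted over the list alone), all 16 heat shock genes (16 up, 0 down adjusted over the list alone), 8 of 9 metallothionein and zinc response genes (8 up, 0 down adjusted over the list alone) and 17 of 23 glycolysis and hypoxia genes (17 up, 0 down adjusted over the list alone). With an estimated correlation these had adjusted p = 0.000196, 0.000146, 0.00475 and 0.000196. Base excision repair genes were lower with CdCl in 9 of 13 and higher in 1 (1 up, 10 down adjusted over the list alone), with adjusted p = 0.00386 (adjusted p = 0.0333 with an estimated correlation). So were 25 of 27 replication genes, with 1 higher (1 up, 25 down adjusted over the list alone), with adjusted p = 4.73e-12 (adjusted p = 0.00475 with an estimated correlation). In all, 3954 genes differed, 1505 higher and 2449 lower with CdCl, or 3620 after median centring, 1828 higher and 1792 lower. The beta-actin 3' minus 5' value averaged 1.71 with CdCl and 1.40 with Di.

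At 48 h the NRF2 targets lay the other way: 25 of 30 were lower with CdCl than with Di and 1 higher (1 up, 25 down adjusted over the list alone), with adjusted p = 4.97e-15 (adjusted p = 0.00253 with an estimated correlation). SRXN1 (-2.05 ± 0.16) and NQO1 (-1.06 ± 0.13) were lower, whereas HMOX1 was higher (0.70 ± 0.19). p53 targets were lower in 16 of 24 and higher in 3 (3 up, 16 down adjusted over the list alone), with adjusted p = 3.76e-06 (adjusted p = 0.00253 with an estimated correlation). GDF15 lay at -1.88 ± 0.19 and CDKN1A at -0.66 ± 0.10. Of the metallothionein list 8 of 9 were higher with CdCl (8 up, 0 down adjusted over the list alone), with adjusted p = 8.83e-18 (adjusted p = 0.00253 with an estimated correlation). MT1M was higher by 7.53 ± 0.23 and MT1X by 3.97 ± 0.14. Mitotic genes were higher with CdCl in 21 of 33 and lower in 1 (22 up, 1 down adjusted over the list alone), with adjusted p = 1.35e-06 (adjusted p = 0.353 with an estimated correlation). In all, 4175 genes differed, 2274 higher and 1901 lower with CdCl (2036 and 2153 of 4189 after median centring), 852 at least 2-fold.

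**Figure D3:**
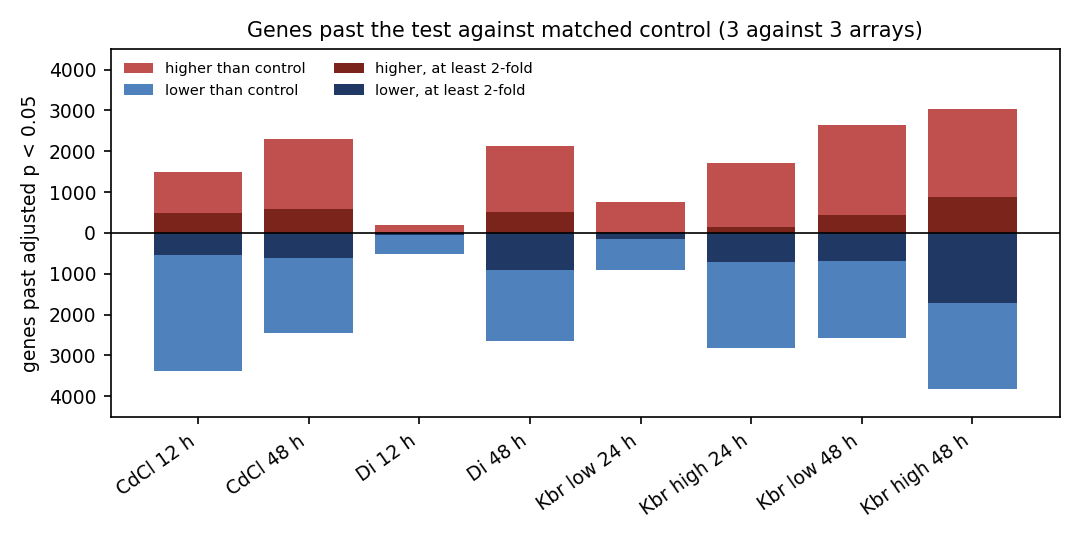
Number of genes past adjusted p under 0.05 in each comparison with matched control (3 arrays against 3), with genes higher than control above 0 and genes lower below it, and darker bars for those changed at least 2-fold. In this fit Di at 12 h has the fewest (695) and Kbr at the high dose and 48 h the most (6855). The order depends on the fit. With only the compared groups, low Kbr at 24 h has 267 against 298 for Di at 12 h, and CdCl at 12 h has 5823 against 5605 for high Kbr at 48 h. Low Kbr at 24 h also has fewer than Di at 12 h with each set fitted alone (933 against 1446) and with array weights (1787 against 2394).

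Whether the effect of a compound differed between times was tested as an interaction. For CdCl the median of all genes moved by -0.13 with centring, from 0.12, and values are relative to it. Its effect was lower at 48 h than at 12 h for ATF3 (-5.34 ± 0.98), SLC7A11 (-4.20 ± 0.60), ZFAND2A (-4.00 ± 0.31) and DDIT3 (-3.62 ± 0.82). A lower effect need not be a fall in treated cells. DDIT3 averaged 11.80 at 12 h and 13.29 at 48 h with CdCl, and 8.07 and 13.06 in the control. Glycolysis and hypoxia genes had a lower effect at 48 h in 14 of 23 (0 up, 14 down adjusted over the list alone) and heat shock genes in 9 of 16 (0 up, 12 down adjusted over the list alone). Their tests gave adjusted p = 1.79e-09 (adjusted p = 0.00733 with an estimated correlation) for the former and adjusted p = 1.58e-08 (adjusted p = 0.0201 with an estimated correlation) for the latter. ATF4 targets did in 12 of 27 (0 up, 12 down adjusted over the list alone), with adjusted p = 1.58e-08 (adjusted p = 0.399 with an estimated correlation), and endoplasmic reticulum chaperones in 7 of 17 (0 up, 8 down adjusted over the list alone), with adjusted p = 0.000177 (adjusted p = 0.487 with an estimated correlation), or adjusted p = 0.113 by the rotation test. In all, 2687 genes passed, 1824 with a higher and 863 with a lower effect at 48 h, against 1047 and 1256 of 2303 after median centring, and 4399 passed with array weights. The effect of Di was higher at 48 h for HMOX1 (4.70 ± 0.27), SRXN1 (3.36 ± 0.22), NQO1 (3.17 ± 0.18) and MAP2 (5.46 ± 0.70), and lower for TMT1A (-4.72 ± 0.62), CCNB1 (-0.99 ± 0.16) and MT1X (-1.41 ± 0.20). NRF2 targets had a higher effect at 48 h in 26 of 30 (28 up, 0 down adjusted over the list alone), and replication and mitotic genes a lower one in 22 of 27 (0 up, 23 down adjusted over the list alone) and 28 of 33 (0 up, 29 down adjusted over the list alone). With an estimated correlation these had adjusted p = 7.52e-05, 0.000612 and 0.0137. In all, 3212 genes passed, 1671 with a higher and 1541 with a lower effect at 48 h, and 4860 passed with array weights. The beta-actin 3' minus 5' values of Di and its control averaged 1.40 and 1.84 at 12 h, as above.

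For the high dose of Kbr, SDF2L1 (3.52 ± 0.76), DDIAS, a gene that limits cell death after DNA damage (2.10 ± 0.49), GDF15 (1.46 ± 0.27) and NQO1 (1.12 ± 0.18) had a higher effect at 48 h than at 24 h. The SDF2L1 value was 4.39 without high-dose 48 h replicate 3. The choline transporter-like gene SLC44A5 (-2.94 ± 0.45) and MT1X (-1.08 ± 0.20) had a lower one. The metallothionein list had a lower effect at 48 h in 7 of 9 (0 up, 7 down adjusted over the list alone), with adjusted p = 2.53e-07 (adjusted p = 0.147 with an estimated correlation). In all, 1663 genes passed, 764 with a higher and 899 with a lower effect at 48 h, or 2668 with the replicate block (1257 and 1411), and 1054 without control 24 h replicate 3. With only the compared groups in the fit 454 passed, MT1X not among them, and 870 with the Kbr set fitted alone. For the low dose SDF2L1 (4.05 ± 0.76), NQO1 (1.47 ± 0.18) and GDF15 (1.47 ± 0.27) had a higher effect at 48 h, and the gap junction gene GJA1 (-2.04 ± 0.42) and FXYD6, a regulator of the sodium pump (-2.12 ± 0.39), a lower one. Without low-dose 48 h replicate 1 or 3 the SDF2L1 value was 3.35 or 5.04. ATF4 targets had a higher effect in 4 of 27 (12 up, 0 down adjusted over the list alone), with adjusted p = 3.73e-09 (adjusted p = 0.264 with an estimated correlation). In all, 482 genes passed, 282 with a higher and 200 with a lower effect at 48 h, 199 and 237 of 436 after median centring, and 1243 with the replicate block (672 and 571). With only the compared groups in the fit 5 genes passed, and with the Kbr set fitted alone 6 did, against 765 with array weights. No gene named here for the low dose passed with only the compared groups, and NQO1 alone of them did with the set alone. The count without single arrays was 110 without control 24 h replicate 3, 226 and 279 without control 48 h replicates 1 and 2, 149 and 252 without low-dose 24 h replicates 1 and 2, and 217, 217 and 949 without low-dose 48 h replicates 1, 2 and 3.

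Across the sets, each treatment was taken against its own control at 48 h before the effects were compared. The CdCl effect exceeded that of high Kbr for MT1M (8.25 ± 0.33), MT1X (4.32 ± 0.20) and HMOX1 (2.41 ± 0.27), and lay below it for DDIAS (-3.53 ± 0.49), CCNB1 (-1.99 ± 0.16) and GDF15 (-1.79 ± 0.27). It was higher in 8 of 9 metallothionein and zinc response genes (8 up, 0 down adjusted over the list alone) and lower in 23 of 27 replication genes (0 up, 24 down adjusted over the list alone) and 31 of 33 mitotic genes (0 up, 32 down adjusted over the list alone). With an estimated correlation these had adjusted p = 0.0213, 0.00884 and 0.0213. In all, 5562 genes passed, 3092 higher and 2470 lower for CdCl (2811 and 2816 of 5627 after median centring). The Di effect exceeded that of high Kbr for SRXN1 (2.37 ± 0.22), HMOX1 (1.71 ± 0.27) and CXCL8 (1.09 ± 0.27), and lay below it for CCNE2 (-3.79 ± 0.22) and CCNB1 (-2.16 ± 0.16). It was lower in 24 of 27 replication genes (0 up, 25 down adjusted over the list alone) and all 33 mitotic genes (0 up, 33 down adjusted over the list alone), with adjusted p = 0.00192 and 0.00286 with an estimated correlation. NRF2 targets were higher for Di in 21 of 30 (22 up, 0 down adjusted over the list alone), with adjusted p = 4.98e-06 (adjusted p = 0.0655 with an estimated correlation). In all, 4830 genes passed, 2623 higher and 2207 lower for Di. The group averages of the beta-actin 3' minus 5' difference were higher in the CdCl and Di set, as given above.

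The vehicle-treated cells of the sets themselves differed at 48 h. The CdCl and Di control exceeded the Kbr control for SDF2L1 (5.25 ± 0.53), ATF3 (4.45 ± 0.69), DDIT3 (3.67 ± 0.58) and HSPA5 (2.47 ± 0.28), and lay below it for the proliferation marker MKI67 (-2.98 ± 0.17) and CCNB1 (-1.25 ± 0.11). Without Kbr control replicate 1 ATF3 stood at 5.04 and DDIT3 at 4.31. All 17 endoplasmic reticulum genes (17 up, 0 down adjusted over the list alone) and 24 of 27 ATF4 targets (24 up, 0 down adjusted over the list alone) were higher. Their tests gave adjusted p = 1.05e-11 (adjusted p = 0.239 with an estimated correlation) for the former and adjusted p = 1.53e-10 (adjusted p = 0.383 with an estimated correlation) for the latter. Replication genes were lower in 25 of 27 and higher in 1 (1 up, 26 down adjusted over the list alone), and mitotic genes were lower in 31 of 33 (0 up, 33 down adjusted over the list alone). With an estimated correlation these had adjusted p = 0.00638 and 0.00638. In all, 5659 genes differed, 2695 higher and 2964 lower in the CdCl and Di control, and the sets also differed in the beta-actin 3' minus 5' value.

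The series counts the 3 compounds as one class by their expression, and at 48 h, the time all 3 share, 1574 genes passed in the same direction with CdCl, Di and high Kbr. Of these 620 rose in all 3 and 954 fell, against 120 and 201 expected of independent lists, which those of CdCl and Di are not, since they share controls. Genes at least 2-fold changed in each numbered 84 up, among them HMOX1, GCLM and NQO1, and 245 down. Between CdCl and high Kbr, which share no control arrays, 952 genes rose with both and 1302 fell with both, against 626 and 842 expected, and 956 moved in opposite directions, against 1458. For Di and high Kbr the counts were 1066, 1685 and 651, against 580, 914 and 1456. Across genes, which are not independent replicates, the log2 differences correlated at r = 0.323 for CdCl with high Kbr and 0.481 for Di with high Kbr.

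Where control arrays are shared, chance alone gives a correlation, and unchanged groups simulated against the same controls had r = 0.499 at 12 h. CdCl and Di correlated at 0.378 at 12 h and 0.663 at 48 h, with a covariance of 0.0726 and 0.350 against a simulated 0.0177 at both times. At 48 h 1149 genes rose with both and 1489 fell with both, against 438 and 584 expected of independent lists, and at 12 h 88 and 361 against 24.8 and 156. The doses of Kbr correlated at 0.924 at 24 h and 0.925 at 48 h, with a covariance of 0.181 and 0.547 against a simulated 0.0177. At 48 h 2316 genes rose and 2473 fell with both doses, against 722 and 886 expected, and 6 moved in opposite directions. Controls of 3 arrays cannot be split so that each part keeps a pair, so part of these overlaps may come from the shared controls.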

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

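Chosen only after the result was seen were the tests on mitotic genes with Kbr, the tests of the control's rise and of RNA quality for the ATF4 and endoplasmic reticulum genes, and the splits with additive effects taken out, with or without keeping the numbers. Effects differed between times, by a test of the difference itself, for 2687 genes with CdCl, 3212 with Di, 1663 with high Kbr and 482 with low Kbr. Single genes with such a difference (later minus earlier effect, log2) were ATF3 (-5.34), SLC7A11 (-4.20), ZFAND2A (-4.00) and DDIT3 (-3.62) for CdCl. For Di they were HMOX1 (4.70), SRXN1 (3.36), NQO1 (3.17), MAP2 (5.46), TMT1A (-4.72), CCNB1 (-0.99) and MT1X (-1.41). High Kbr gave SDF2L1 (3.52), DDIAS (2.10), GDF15 (1.46), NQO1 (1.12), SLC44A5 (-2.94) and MT1X (-1.08). Low Kbr gave SDF2L1 (4.05), NQO1 (1.47), GDF15 (1.47), GJA1 (-2.04) and FXYD6 (-2.12). Of 100 random splits of the same arrays into groups of the same sizes, 8 gave as many genes for CdCl, 8 for Di, 11 for high Kbr and 14 for low Kbr, the real one included. The highest other counts were 4288, 5326, 5480 and 4027, which points to a structure of the samples, since such splits mix treated with control and early with late arrays. They thus carry the effects of treatment and of time themselves, and do not test the difference between effects. With additive effects of treatment and time taken out first, the numbers with as many genes were 2, 2, 1 and 4 of 100, with highest other counts of 2773, 3384, 1083 and 976. Regrouped only among arrays of the same number, the Kbr set gave 1 and 1 of 100, the real one, with highest other counts of 1263 and 198. By these later tests chance can be excluded for the count of high Kbr, as far as tests chosen after the first splits allow. For CdCl and Di a random regrouping gave more genes than the real grouping, so chance is made less likely but is not excluded. For low Kbr it stays open. Both the counts of the first splits and those of the later ones depend on the draw, so values near 5 in 100, as for CdCl and Di in the first and low Kbr in the later, may fall on either side in another. The low Kbr count was 5 with only the compared groups in the fit and 6 with the Kbr set fitted alone.

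At 48 h the effect of CdCl differed from that of high Kbr in 5562 genes, among them MT1M (8.25), MT1X (4.32), HMOX1 (2.41), DDIAS (-3.53), CCNB1 (-1.99) and GDF15 (-1.79). The effect of Di differed from it in 4830, among them SRXN1 (2.37), HMOX1 (1.71), CXCL8 (1.09), CCNE2 (-3.79) and CCNB1 (-2.16). Of 100 splits 1 gave as many genes for each, the real one, with 4800 and 4603 in the highest other. These splits too carry the main effects. With additive effects taken out first the number was again 1 of 100 for each, with 3365 and 2729 in the highest other. That regrouping was chosen after the first splits and mixed arrays of both sets, of which those of Kbr go together by number. Chance is thus made less likely but is not excluded.

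Mitotic genes were higher than control with both doses of Kbr at 48 h, and with both at 24 h (list medians 0.37 for the high and 0.31 for the low dose, with 18 and 11 of 33 members passing), whereas they were lower with CdCl and Di at 48 h. With an estimated correlation none of the 4 list calls with Kbr held (adjusted p = 0.205 and 0.122 for high and low at 48 h, 0.207 and 0.114 at 24 h). With the replicate block as well, that of the low dose at 24 h held (adjusted p = 0.0298). Those of the high dose at 24 h (0.0699) and of the high and low dose at 48 h (0.0789 and 0.0600) did not. The median for the high dose at 48 h was 0.66 as deposited and at least 0.65 with arrays centred or quantile normalized, so a further scaling hardly moved it. The authors had already normalized these values, so this cannot test that step itself. From 24 h to 48 h the median change was -0.65 in the control and -0.40 in high-dose cells, and the high dose at 48 h lay 0.0383 from the control at 24 h (SE over members 0.07; 7 higher, 5 lower and 21 not passing). A deeper fall in the control may thus account for part of the difference at 48 h, but not for the one already present at 24 h, and at 48 h cannot be told apart from a rise set by Kbr, since both are the same difference. The 48 h control of the CdCl and Di set lay at -1.62 against that of the Kbr set, and since each compound was run in 1 set, compound and set cannot be told apart.

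ATF4 targets and endoplasmic reticulum chaperones had a lower effect of CdCl at 48 h than at 12 h (adjusted p = 1.58e-08 and 0.000177 as lists, but 0.399 and 0.487 with an estimated correlation, so neither call held), the chaperones still passing upward at 48 h as a list (adjusted p = 0.0439, or 0.726 with an estimated correlation) and the ATF4 targets not. Arrays centred or quantile normalized gave a median difference between the effects of -0.9998 or lower (-0.95 as deposited), so a further scaling did not remove it. Made on values already normalized by the authors, this cannot test that step itself. The beta-actin 3' minus 5' value of the control had a difference of -0.34 at 48 h against 12 h (larger SD of the groups 0.14). This is the direction of better RNA at 48 h, which argues against RNA decay in that control at 48 h. The value still differed between the times, and whether that difference moved these genes was not tested. The members were higher in the control itself at 48 h than at 12 h, by a median of 2.14 and in 44 of 44 members, of which 17 of 17 chaperones and 24 of 27 ATF4 targets passed, and were higher by 1.01 in CdCl cells (40 members), by 2.36 in Di cells (43), and by 0.13 in the Kbr control from 24 h to 48 h (29). The smaller difference at 48 h may thus come from a rise in the reference cultures, and what raised these genes there was not tested.

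Same-numbered arrays of the Kbr set deviated together, the lowest correlation being 0.218 and the median 0.456. With ATF4 and endoplasmic reticulum genes and those that follow them closely left out, 7231 genes still gave at least 0.142. Genes that follow them less closely stayed in, so this cannot decide whether a stress state of the cultures is the whole source. Taking the beta-actin 3' minus 5' difference out of each gene gave a lowest correlation of -0.210 (median 0.186), and taking out the array median gave -0.417 (median 0.315). The beta-actin value was itself highest in replicate 2 of every Kbr group, so taking it out lowers the correlation whatever its source. That step therefore gives no support to RNA quality. RNA quality and the overall level of an array stay open as sources of part of it. A shared day of culture or processing, which the labels do not give, stays open too, and no biological explanation other than that stress state was tested.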

How the results depend on the processing

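The fits of 1 set of arrays alone, with or without the replicate block, the estimated correlation with that block, and the comparisons over time within controls were chosen after seeing the data. Of 248 recomputed gene counts 39 moved by over 1.5 times, as did 23 of 177 with an array left out, and none of the others did. With only the compared groups in the fit, Di at 12 h called 298 genes, low Kbr 267 at 24 h and 3445 at 48 h, the doses 38 at 24 h and 647 at 48 h, the change over time 454 for high and 5 for low Kbr and 4 for the Kbr control. Array weights gave 2394 for Di at 12 h, 4399, 4860 and 765 for the change over time of CdCl, Di and low Kbr, and 767 for the Kbr control. The replicate block gave 1662 for Di at 12 h, 2720 for low Kbr at 24 h, 1171 for the doses at 24 h, 2668 and 1243 for the change over time of high and low Kbr and 2498 for the Kbr control. The set alone gave 1446, 933, 108, 870, 6 and 633 for the same 6 results, and the Kbr set alone with the block 2649, 1020, 2562, 741 and 2513 for the last 5. A threshold of 0.01 gave 211 for Di at 12 h, 777 for low Kbr at 24 h, 145 and 1571 for the doses at 24 h and 48 h, 1400, 2058, 750 and 76 for the change over time of CdCl, Di, high and low Kbr and 535 for the Kbr control. Leaving out 1 array gave 286 to 613 for Di at 12 h, 824 to 1882 for low Kbr at 24 h, 196 to 378 for the doses at 24 h, 1054 to 2127 and 110 to 949 for the change over time of high and low Kbr and 387 to 1765 for the Kbr control. For all of these but the threshold the cause was not tested.

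Of 199 values of named genes, 182 kept their direction and side of the threshold under every alternative run, 0 changed direction, and 17 lost the call with only the compared groups in the fit and 4 with a set alone. Of 245 list results 0 changed direction; quantile normalization ended 7 calls and added 4, the mean of probe sets ended 4 and added 5, a filter at 6 ended 2 and added 1, the replicate block ended 3 and added 5, a variance trend ended 0 and added 2, and an estimated correlation ended 82. Leaving out single arrays ended a list call in 39 refits and added one in 16, and ended no gene call given here. Of the list calls given here, it ended that of the endoplasmic reticulum chaperones with CdCl at 48 h. Tests of the lists' own members with fry ended 8 calls and added 36 for direction, and ended 9 and added 70 for change either way. In the Kbr set the block changed no other call of a count, gene or list given in the text than those given beside it. In the CdCl and Di set the arrays shared only a number: deviations of same-numbered arrays correlated at -0.348 to 0.416, and 3 of 18 lay closest to their own number. Signal near background limits the values of dim genes, of which only bounds are given.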

Other observations

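The changes over time within the vehicle-treated cells were compared only after the data had been seen. In the control of CdCl and Di, ATF3 rose by 5.52 ± 0.69 from 12 h to 48 h on the log2 scale, DDIT3 by 4.99 ± 0.58, INHBE, an inhibin subunit induced by stress in the endoplasmic reticulum, by 5.30 ± 0.70 and HSPA5 by 1.82 ± 0.28. All 17 endoplasmic reticulum genes (17 up, 0 down adjusted over the list alone) and 24 of 27 ATF4 targets (25 up, 0 down adjusted over the list alone) rose. The set test gave adjusted p = 8.98e-13 (adjusted p = 0.230 with an estimated correlation) for the former and adjusted p = 4.76e-16 (adjusted p = 0.230 with an estimated correlation) for the latter. All 33 mitotic genes (0 up, 33 down adjusted over the list alone) and 26 of 27 replication genes (0 up, 26 down adjusted over the list alone) fell, CCNB1 at -1.83 ± 0.11 and MCM10, a replication factor, at least 12.8-fold. Set tests gave adjusted p = 3.54e-30 (adjusted p = 0.00206 with an estimated correlation) for mitosis and adjusted p = 3.19e-20 (adjusted p = 0.00104 with an estimated correlation) for replication. TXNIP was at least 58.5-fold lower. In all, 5064 genes passed, 2032 higher and 3032 lower at 48 h, or 2591 and 2476 of 5067 with arrays centred on their medians. The beta-actin 3' minus 5' value of this control averaged 1.84 at 12 h, and its difference at 48 h from that was -0.34.

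In the Kbr control, TXNIP fell by 3.48 ± 0.43 from 24 h to 48 h and the collagenase MMP1 fell by 2.89 ± 0.39, while the proteinase ADAMTS5 rose by 2.36 ± 0.37 and the transporter SLC6A13 by 2.34 ± 0.29. Without control 48 h replicate 1 TXNIP lay at -2.71 and MMP1 at -2.22. Mitotic genes fell in 25 of 33 (0 up, 31 down adjusted over the list alone), with CCNB1 at -0.81 ± 0.11, and replication genes in 15 of 27 (0 up, 22 down adjusted over the list alone). Here the tests gave adjusted p = 1.19e-21 (adjusted p = 0.0166 with an estimated correlation) for mitosis and adjusted p = 7.35e-11 (adjusted p = 0.0166 with an estimated correlation) for replication, the latter 0.0720 with the estimated correlation and the replicate block. In all, 1358 genes passed, 564 higher and 794 lower, 650 and 585 of 1235 with median centring, and 2498 with the block (978 and 1520). Only the compared groups in the fit gave 4, none of them a gene named here, the Kbr set fitted alone 633 and array weights 767. Without control 24 h replicate 3 the count was 387, and without control 48 h replicate 1 or 2 it was 561 or 785.

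For comparisons of 3 arrays with 3, the 10 splits of the 6 arrays are too few for a share under 0.05. In each, 1 split gave as many genes, the real one. Against their controls, CdCl called 4870 genes at 12 h and 4735 at 48 h, with 2 and 8 in the highest other split, and Di 695 and 4773, with 6 and 5. High Kbr called 4517 at 24 h and 6855 at 48 h, with 2 and 82, and low Kbr 1687 and 5212, with 6 and 108. The doses differed in 487 genes at 24 h and 2638 at 48 h, with 0 and 1063, and CdCl and Di in 3954 at 12 h and 4175 at 48 h, with 15 and 17. The 48 h controls differed in 5659, with 5, the CdCl and Di control over time in 5064, with 1, and the Kbr control over time in 1358, with 132. Within the Kbr set, the 4 splits that keep 1 array of each number on each side, as the real one does, gave 0 genes in the highest other split of every such comparison. The larger counts came from splits that put both arrays of a number on one side. For genes changed alike by all 3 compounds (1574), 1 of 100 splits gave as many, the real one, and the highest other count was 1. Such splits remove the differences within each comparison, so they do not test whether the lists overlap by more than chance.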
